A study of Arabidopsis thaliana with 28 samples.

How the data were processed

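Chromatin accessibility was measured by ATAC-seq in 16 Arabidopsis samples: WT (Col-0) roots with 4 control and 4 BA libraries, WT shoots with 2 and 2, and arr1,10,12 roots with 2 and 2. The series text calls them biological replicates. Per the labels' protocols, tissue was kept for 45 min in MS liquid medium with vehicle or 5 µM BA, nuclei were collected on sucrose cushions, stained with DAPI and sorted by fluorescence, and open DNA was tagged with Tn5 transposase. The series has 28 samples; its 12 RNA-seq samples were not analysed here. Per the submitters' processing notes, Bowtie 1.2.0, SAMtools 1.5, deepTools 2.5.2 and HOMER 4.9.2 were used with the build TAIR10; the role of each tool and its parameters are not stated. The deposited files used here are 16 peak lists, 1 per library, and 2 lists of differential regions, 1 for roots and 1 for shoots, whose file names give diffReps and a fold of 1.2. All hold chromosome, start and end. They hold no score, height, fold, direction, p or read number, so depth per sample is unknown and no precision from counting can be given. The differential lists lie on a grid of 20 bp. The peak lists hold the 5 nuclear chromosomes.

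The gene table names the assembly TAIR10.1, while the files are on TAIR10. It was checked against the peaks in 59 bins of 2 Mb: in 59 of 59 the offset that put most gene flanks under a peak was within 100 bp of 0 (largest 50 bp). Coordinates are printed from the files alone. The table gives 27432 protein-coding genes on the nuclear chromosomes and no strand. Several measures written before the data were examined therefore had to be replaced: windows upstream of the start of transcription became the gene body with 1 kb on both sides, and the nearest gene became the one over the midpoint or with the nearest end. Positions were classed by the midpoint as gene body, within 1 kb of a gene, or elsewhere, with protein-coding genes alone. A planned count of type-B regulator binding motifs was not run, as no genome sequence was used here.

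Peaks of a comparison were merged where they overlapped, and regions with a peak in at least 2 libraries were kept. Each region was tested by a two-sided Fisher's exact test of libraries with and without a peak, adjusted by Benjamini-Hochberg (threshold 0.05), and counted as fully separated when all libraries of one side and none of the other had a peak. Library values (number, covered length and median width of peaks, classes of position) and list means were compared by two-sided exact permutation over all splits of the libraries, adjusted within a comparison. Similarity was the Jaccard index over base pairs, with a one-sided exact permutation test. The smallest two-sided p is 0.0286 for 4 against 4 libraries, 0.00202 for 8 against 4 and 0.333 for 2 against 2, so that for shoots and for arr1,10,12 roots BA and control are given as values. In WT roots, deviations of each library from the mean of its treatment were compared between BA and control. Those of the same replicate number were correlated at 0.182 to 0.335. Those of other numbers had -0.223 to 0.134, values that removal of the mean lowers. The numbers thus pair these libraries, and labels were also permuted within pairs, where the smallest exact p is 0.125. The permutations of 8 against 4 libraries, and the Fisher tests of single regions, do not keep pairs together; only 15 splits do, for which the smallest share is 0.0667.

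Differential regions were ranked by width and given a direction from the mean covered percent in BA and control libraries of their own tissue, where any difference counted, however small. As the authors chose the regions on these libraries, the direction is a description. The overlap of the lists was compared with 10000 seeded draws from WT peak regions on the same chromosomes. The covered percent was then read in the other tissue and in arr1,10,12, and differences between effects were tested by permuting BA and control labels within each set of libraries.

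There were 9 gene lists, fixed before the data were examined: type-A ARRs, type-B ARRs, receptors and phosphotransfer proteins, cytokinin metabolism, cytokinin response factors and other early response genes, auxin transport and response, root identity, photosynthesis and leaf identity, and broadly used genes. All 135 locus IDs were found in the gene table, and PIN2 is in 2 lists. Genes with a differential region in the window were counted against other protein-coding genes with a peak in that tissue by a one-sided Fisher's exact test, adjusted over 18 tests. As the windows of most list genes held a peak, the covered percent of the window was added as a measure after the data were seen. Families of 8 or more genes sharing a symbol stem were also added then. A rule for naming genes was written before the data were examined: cytokinin list members with a differential region, the 10 widest regions per direction and tissue, the 10 separated regions per direction with the widest peaks for tissue and genotype, list members with an unadjusted Fisher p under 0.05, the 10 longest overlaps of the lists, and ARR1, ARR10 and ARR12. Not all named genes follow it. List members named by the covered percent of the window, and genes outside the lists picked under other observations, were chosen after the data were seen.

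Alternatives were peaks at least as wide as the median, the same number of widest peaks per library, merging within 150 bp, regions in at least 3 libraries, at least 50% of a region covered, control libraries alone, 2 kb flanks, other backgrounds and overlaps, subtraction of the mean over all regions, permutation within pairs, and each library left out in turn. Added after the data were seen were the gene body alone, 0.5 kb flanks, and both WT root libraries of replicate 1 left out together. Regions matched to the differential ones on covered percent in WT, width and width of the peak region were drawn 1000 times. On simulated data with 8 against 4 libraries, 3000 planted regions gave 3000 calls in both comparisons, and 200 planted regions gave 0. All planted regions were fully separated. The outcome follows from the separated regions that the adjustment needs (1293 for tissue and 1249 for genotype). Partial differences were not simulated. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.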

Results

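Open chromatin was mapped by ATAC-seq, in which a transposase tags accessible DNA, in sorted nuclei of Arabidopsis roots and shoots after 45 min of treatment with 5 µM benzyladenine (BA), a cytokinin, or with vehicle. Wild-type (WT, Col-0) roots had 4 BA and 4 control libraries. WT shoots had 2 and 2. Roots of arr1,10,12, a mutant in the type-B response regulators ARR1, ARR10 and ARR12, which are the transcription factors at the end of the cytokinin pathway, also had 2 and 2. The 16 peak lists held between 30778 peaks (shoot control 2) and 36358 peaks (root control 1). Peaks covered 19.7 to 28.7 Mb of the 5 nuclear chromosomes. The lists give coordinates without read numbers, so the sequencing depth is unknown and no counting interval can be given. A further 12 RNA-seq samples, 3 in each of 4 groups, were not analysed here. The authors' 2 lists of regions with differential accessibility between BA and control, 1 for roots and 1 for shoots, give no fold or direction. A region is therefore described by the percent of its length under a peak in each library (covered percent), and a gene by the covered percent of its window, which is the gene body with 1 kb on both sides. Coordinates are those of the TAIR10 build. Outside the gene lists, a region carries the name of the protein-coding gene over its midpoint or nearest to it. That gene can lie over 1 kb away. Errors are SD between libraries.

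The first question was where chromatin accessibility differed between BA and control in WT roots. The authors' root list included most type-A response regulator genes and some other genes of the cytokinin pathway. A wide region lay within 1 kb of ARR5, a type-A response regulator that cytokinin induces and that dampens the pathway (chromosome 3, 17759903 to 17762260). It was 89.2% ± 7.4 covered in control and 100% in all 4 BA libraries. At ARR7, another type-A regulator, a region in the flank (chromosome 1, 6580023 to 6580560) was 45.9% ± 10.4 covered in control and 100% with BA (n = 4 each). Next to ARR16 a region of 258 bp (chromosome 2, 16969303 to 16969560) had a peak in 2 of 4 control and 4 of 4 BA libraries.

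The list held 760 regions with a median width of 258 bp, 259.5 kb in all. Of these, 296 were more covered with BA, 51 were less covered, and 413 were fully covered in every WT root library, so that the peaks give them no direction. Among the regions with a direction, 85.3% were more covered with BA. The regions were chosen by the authors on these libraries, so this is a description and not a test. Regions with the midpoint more than 1 kb from any protein-coding gene made up 30.8% of the list against 15.8% of the 30562 regions with a peak in at least 2 WT root libraries (Fisher's exact test, two-sided, adjusted p = 1.48e-23). Those with the midpoint in a gene body made up 32.2% against 42.0% (exact test, adjusted p = 1.5e-07), and those with it within 1 kb of a gene 37.0% against 42.2% (exact test, adjusted p = 0.00557). The regions of the list were narrower (median 258 against 713 bp), and several can lie at the same gene. The test takes each as independent, so these p-values are too small where that fails.

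Of the 10 type-A genes, 9 had a root differential region in the window (ARR3, ARR4, ARR5, ARR6, ARR7, ARR8, ARR9, ARR16 and ARR17), against 2.4% of other genes (one-sided Fisher's exact test, adjusted p = 4.97e-13 over 18 tests). Regions without a direction were among those of ARR3, ARR4, ARR5, ARR8 and ARR9. The other ARR9 region was less covered with BA (100% to 98.0%), and each other gene named had a region that was more covered. Among 9 genes of cytokinin receptors and phosphotransfer proteins, the receptor gene AHK4 and the phosphotransfer genes AHP1 and AHP3 had a root differential region (exact test, adjusted p = 0.00278). Each of these regions was 100% covered in control and with BA and so without a direction. The AHP3 region lay in the flank of AHP3, with its midpoint in the body of the neighbour AT5G39330. Of 21 genes of cytokinin metabolism, 5 had a root differential region (exact test, adjusted p = 0.000742): CKX4, CKX5 and CKX6, which encode cytokinin-degrading oxidases, CYP735A2, which makes trans-zeatin type cytokinins, and LOG7, which releases active cytokinin. Of 14 response factors and other early response genes, 4 had one (exact test, adjusted p = 0.00129): LBD3, the auxin response repressor IAA3, the F-box gene CFB and HBI1. In the auxin list IAA17, another repressor of auxin response, was the 1 gene of 14 (exact test, adjusted p = 0.525), and in the photosynthesis list PSAF was the 1 gene of 25 with a root peak (exact test, adjusted p = 0.753). No gene had a region among 8 type-B regulators, 19 root identity genes and 7 broadly used genes (exact test, adjusted p = 1 for each). Over all 225 families of gene symbols, 0 of 435 Fisher tests in roots and shoots passed the adjustment and 22 had an unadjusted p under 0.05. The stems split some families, as the gene table spells some response regulators RR and others ARR. In roots the RR stem counted ARR16, ARR8, ARR5 and ARR17, 4 of 13 genes (Fisher's exact test, adjusted p = 0.056). These tests therefore do not cover the type-A genes as a family.

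**Figure D1:**
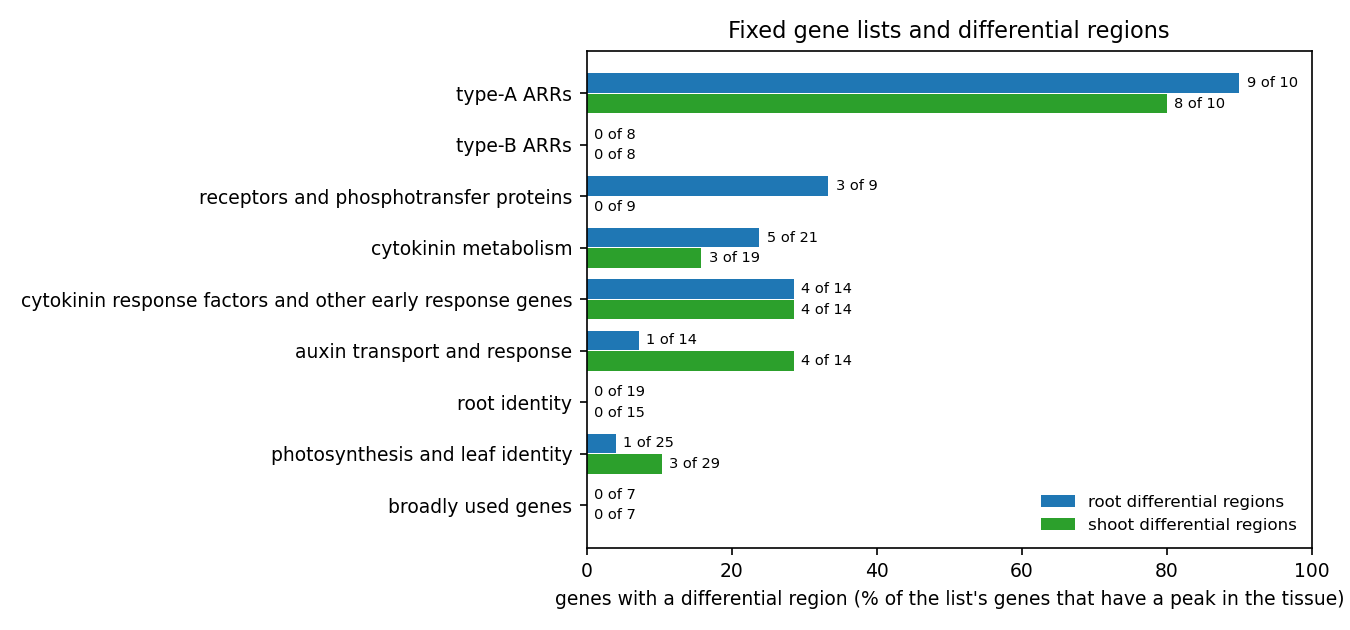
Percent of the genes of each fixed list (horizontal axis, % of the genes with a peak in the tissue) whose window holds a differential region, for the root (blue) and the shoot list (green); the numbers beside the bars are genes. Type-A ARR genes stand at 9 of 10 in roots and 8 of 10 in shoots, and type-B ARR genes at 0 of 8 in both.

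The other wide regions that were more covered with BA lay at AT1G64590 (3638 bp, 97.9% ± 1.9 to 100%), AT4G25410, AT2G24580, CFB (1558 bp, 94.5% ± 6.4 to 100%), AT5G51780, AT5G41590, IAA17 (1118 bp, 94.1% ± 2.5 to 99.9% ± 0.22), AT2G20080 and GDH1, a glutamate dehydrogenase gene. The widest that were less covered lay at NIP5;1, a boron channel gene (chromosome 4, 6431383 to 6432080), which went from 100% to 96.0% ± 2.7, and at AT2G41890, AT5G58900, AT5G25360, the invertase gene ATBFRUCT1, AZI1, AT1G09245, IBH1, the nitrate transporter gene NRT1:2 and AT1G77330. Of these, AT5G25360 differed most, from 100% to 80.2% ± 4.7 (n = 4 each). Others differed little, such as ATBFRUCT1 (99.5% to 98.9%) and AT1G09245 (98.5% to 97.7%). The regions named by AZI1 and IBH1 had no protein-coding gene within 1 kb. Wide regions without a direction lay at ARR5, ARR4, ARR9, AT5G51780, AT1G58170, AT1G11670, NPY5 and TIP2, and over 1 kb from CYP705A5.

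Averaged over the 10 type-A genes, 51.0% ± 2.1 of the window was covered in control and 64.0% ± 4.6 with BA (n = 4 each, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.257 over 9 lists), and all 10 genes had the higher mean with BA. ARR7 had 35.9% ± 3.0 in control and 81.1% ± 10.6 with BA. ARR16 had 3.33% ± 3.9 and 25.0% ± 6.8, and CYP735A2 27.7% ± 7.8 and 49.3% ± 19.4. CKX4 had 64.5% ± 1.6 and 78.3% ± 6.6, LBD3 46.0% ± 4.8 and 57.4% ± 4.7, and IAA17 48.2% ± 7.7 and 65.6% ± 5.3. ARR17, CFB and LOG8 made 9 genes at this smallest exact p of 0.0286, of which LOG8 was lower with BA, 28.2% ± 3.6 against 20.8% ± 3.8. None passed when adjusted over the list alone, and of the 9 only ARR7 and CFB kept an unadjusted exact p under 0.05 when each library was left out in turn. The differences for the other lists were -0.889 percentage points for type-B genes, 0.225 for receptors and phosphotransfer proteins, 0.512 for metabolism, 1.41 for early response, -1.96 for auxin, -4.22 for root identity, -1.50 for photosynthesis and -1.79 for broadly used genes, with exact permutation p between 0.0857 and 0.8. Every replicate pair was higher with BA for the type-A list and lower for root identity and photosynthesis. Within pairs the exact p of these lists was 0.125, the smallest possible, and 0.375 to 0.875 for the others. WT root peaks also covered less in general with BA (25.5 ± 1.2 against 27.2 ± 1.4 Mb in control). No list was tested against that general difference.

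Seen as presence or absence of a peak, the treatments separated few regions of the root libraries. Of 30562 regions, 8 had a peak in all 4 BA and no control library and 18 the reverse, and 21614 had one in all 8 libraries. The number of regions separated by BA and control, WT roots, thus 26, was 41 to 90 without any 1 library and 172 without both replicates 1, where fewer libraries have to differ. By Fisher's exact test, 26 regions had an unadjusted p under 0.05 and 0 passed the adjustment, which 4 against 4 libraries cannot reach at this number. Peak sets had a Jaccard index of 0.795 between treatments and 0.793 within them (one-sided exact permutation p = 0.629). Libraries of the same replicate number, which raise the value between treatments, had 0.819 and those of other numbers 0.790; within replicate pairs the exact p was 0.125, the smallest possible. BA and control libraries had 33029.5 ± 1479 and 33591.5 ± 1859 peaks (exact permutation p = 0.486) covering 25.5 ± 1.2 and 27.2 ± 1.4 Mb (exact p = 0.143). Peaks had a median width of 506 ± 13 and 530.8 ± 6.0 bp (exact p = 0.0286, adjusted p = 0.171). All 3 values were lower with BA in 4 of 4 replicate pairs (exact p = 0.125 within pairs, the smallest possible, for each). The peak number, BA against control, WT roots (-562), turned positive without control 1 (360.2), the library with the most peaks.

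The same question was asked of WT shoots. Wide regions lay at several type-A genes, and with 2 libraries per treatment the values are given without a call, since the smallest exact p is 0.333. A region of 4258 bp over ARR5 (chromosome 3, 17757903 to 17762160) was 68.3% ± 1.5 covered in control and 100% with BA. A region of 2478 bp that touches the body of ARR7 and has its midpoint nearest to the neighbour AT1G19040 (chromosome 1, 6575983 to 6578460) was 34.6% ± 16.8 covered in control and 100% with BA (n = 2 each). At ARR15, a region of 298 bp (chromosome 1, 28131023 to 28131320) had no peak in control and was 89.1% ± 6.4 covered with BA.

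The shoot list held 685 regions, 215.2 kb in all, with a median width of 238 bp. Of these, 308 were more covered with BA, by a mean of 34.7 percentage points, 23 were less covered, and 354 were fully covered in every shoot library. Those with a direction were 93.1% more covered with BA. Regions with the midpoint more than 1 kb from any protein-coding gene made up 21.9% of the list against 15.7% of the 28755 shoot regions (Fisher's exact test, adjusted p = 5.59e-05). By the same exact test the shares in gene bodies (40.1% against 42.6%, adjusted p = 0.211) and within 1 kb (37.96% against 41.7%, adjusted p = 0.06) did not pass. The limit on independence given for roots holds here too.

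Of the 10 type-A genes, 8 had a shoot region (ARR4, ARR5, ARR6, ARR7, ARR8, ARR9, ARR15 and ARR16; one-sided Fisher's exact test, adjusted p = 1.47e-10, against 2.8% of other genes). In the metabolism list these were CKX4, CKX5 and the glucosyltransferase gene UGT76C2, 3 of 19 genes with a shoot peak (exact test, adjusted p = 0.0347). In the early response list they were CRF2, CRF6, LBD3 and the D-type cyclin gene CYCD3;1, 4 of 14 (exact test, adjusted p = 0.0015). In the auxin list they were the efflux carrier genes PIN3, PIN4 and PIN7 and IAA2, 4 of 14 (exact test, adjusted p = 0.0015), where the PIN3 region was less covered with BA (100% to 55.6%) and the others had no direction. LHCB2.1, RBCS1A and RBCS2B had one in the photosynthesis list, 3 of 29 (exact test, adjusted p = 0.0946), and no gene did among 9 receptors and phosphotransfer proteins, 8 type-B regulators, 15 root identity genes and 7 broadly used genes (exact test, adjusted p = 1 for each). With 2 kb on both sides of the gene the metabolism list did not pass, and with the gene body alone, a window chosen after the data were seen, the early response list did not.

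The covered percent went from 18.6% ± 26.3 to 96.0% ± 0.66 in a region of LBD3, from 28.1% ± 39.8 to 100% in one of CKX4, from 22.8% ± 32.2 to 100% in one of CKX5, and from 63.9% ± 21.8 to 100% in one of CYCD3;1. Other wide regions that were more covered with BA lay at ARR9 (2298 bp), ARR7 (1558 bp), ARR4 (1418 bp), ARR6 (1278 bp, 56.5% ± 30.8 to 100%), AT5G46220, CKX5 (1018 bp) and AT1G69030. Regions that were less covered with BA lay at AT5G40450 (chromosome 5, 16185123 to 16185640, 100% to 33.2% ± 28.4), EXL3 (100% to 72.5% ± 0.25 in one of its regions) and MYB112 (90.7% ± 13.2 to 42.4% ± 1.4). Others lay at AT1G16850, AT1G28327 and AT1G03457, and over 1 kb from AT2G26690, AT2G06845 and AT5G28300. Some of these differed little, such as AT1G16850 (100% to 99.7%) and AT1G03457 (99.1% to 97.1%). Wide regions without a direction lay at FLA2, AT1G68500, the proline dehydrogenase gene ERD5, IAA2, CAT6, ML5, AT5G28300, AT5G25280 and AT5G42090, and over 1 kb from ACR8. Over the type-A windows the covered percent was 44.4% ± 5.1 in control and 59.4% ± 3.1 with BA. In shoots 631 of 28755 regions separated the treatments, and the other splits of the 4 libraries separated 647 and 1647.

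**Figure D2:**
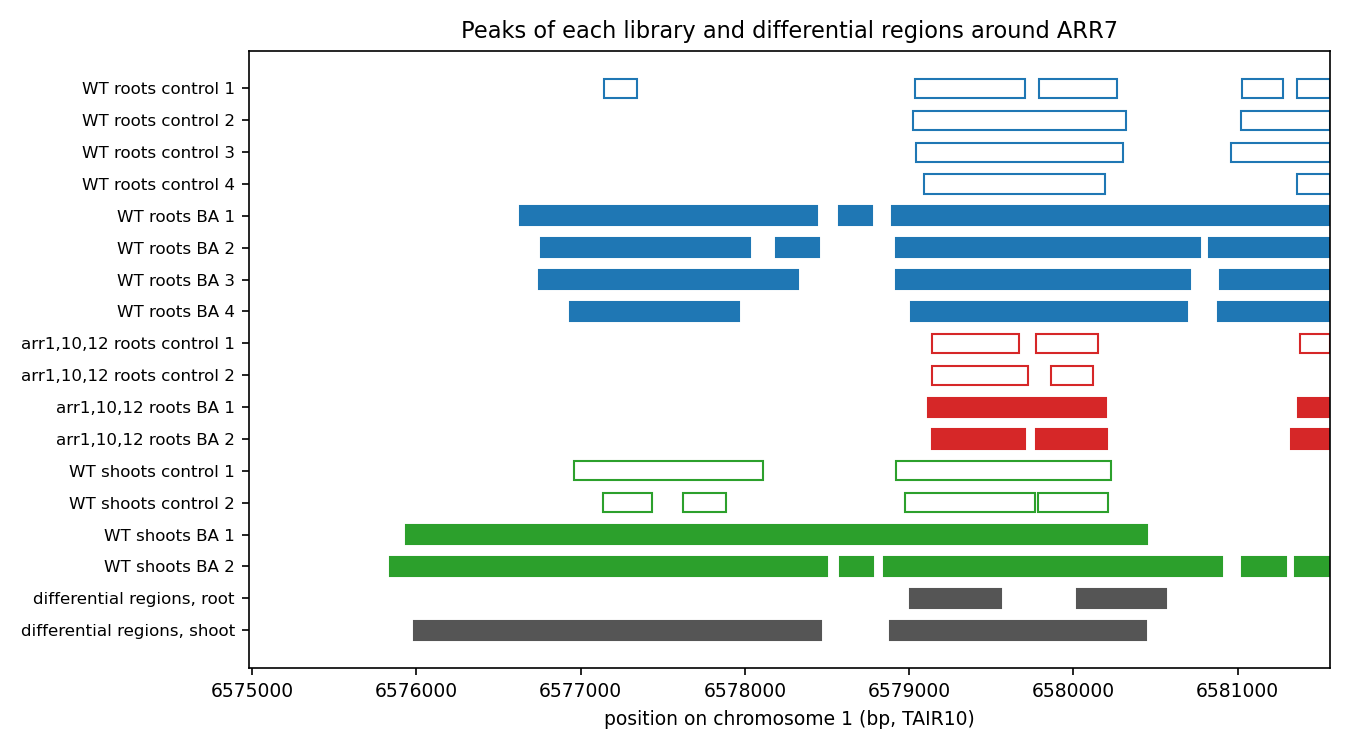
Peaks of the 16 libraries and the differential regions of both lists around ARR7 (horizontal axis, position on chromosome 1 in bp, TAIR10); filled bars are BA libraries, open bars controls, in WT roots (blue), arr1,10,12 roots (red) and WT shoots (green). The region from 6575983 to 6578460 has a peak in 4 of 4 WT root BA libraries, 1 of 4 WT root controls and 0 of 4 arr1,10,12 libraries.

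The title of the series speaks of a response that depends on context, so the lists of roots and shoots were compared. The longest overlaps of the lists lay at ARR5, ARR6, ARR9, ARR4, ARR7, CKX5, LBD3 and AT5G41590. Shorter overlaps lay at other genes, such as AT1G58170. AHK4, AHP1 and AHP3 had regions in the root list alone, and PIN3, PIN4 and PIN7 in the shoot list alone. A difference between the lists in these genes was not tested. Of the root regions, 89 (11.7%) overlapped a shoot region, against a mean of 5.6 in 10000 random draws from WT peak regions (highest 17, one-sided permutation p = 0.0001, the smallest possible). Among 93 overlapping pairs, 35 were more covered with BA in both tissues, 0 were less covered in both, 1 had opposite directions and 57 had no direction in at least 1 list. By gene, 597 had a root region, 660 a shoot region and 90 both.

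Each list was then read in the other tissue. As the authors chose each list on its own tissue, some lower coverage in the other follows from the choice. The 760 root regions were 59.1% ± 4.0 covered in the 4 shoot libraries, and 594 had a peak in any of them. The CFB region of 1558 bp, 94.5% ± 6.4 covered in root controls, had a mean of 0.193% ± 0.27 in shoot controls and no peak in shoots with BA. In shoots the root regions were 56.3% ± 1.3 covered in control and 61.9% ± 3.8 with BA, and windows matched to them on WT root libraries 74.0% and 74.8%. The 685 shoot regions in WT roots were 79.5% ± 1.0 covered in control and 80.3% ± 3.0 with BA (n = 4 each, exact permutation p = 0.629). For shoot differential regions, BA minus control in WT roots was 0.828, and -0.173 without root BA replicate 1. After subtraction of the mean over all regions it was 6.94 (exact permutation p = 0.0571). Windows matched on shoot libraries were 84.96% covered in root controls, and their difference was -2.13 (central 95% of 1000 sets -2.87 to -1.38), below the regions. In shoots the regions differed by 14.6 and the matched windows by 14.2, a likeness set by the matching on shoot control and BA. As the authors chose the regions on the shoot libraries, a test between the 2 tissues would restate the choice and is not given. The ARR7 region from 6575983 to 6578460 was 2.02% ± 4.0 covered in root controls and 60.02% ± 13.3 with BA, and an ARR16 shoot region of 798 bp 16.8% ± 19.4 and 89.4% ± 8.6.

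The next question was what the loss of ARR1, ARR10 and ARR12 did to the root landscape and to its response. On average the root differential regions were less covered in the mutant, though not all of them. The mean was lower in the mutant in 347 regions, the same in 331 and higher in 82, and 7 had no peak in any mutant library. The 760 regions were 97.6% ± 1.9 covered in the 8 WT root libraries and 89.99% ± 2.1 in the 4 arr1,10,12 libraries (difference 7.59 percentage points, exact permutation p = 0.00202, the smallest possible, adjusted p = 0.00909 over 18 tests), with every mutant library below every WT library. This p, like every other p of 8 against 4 libraries, takes the libraries as unpaired; only 15 splits keep replicate pairs together, and their smallest share is 0.0667. The authors chose the regions on the WT libraries, and 413 were fully covered in each of them, so that higher mutant values were ruled out for most. The choice thus favours a lower mutant mean, and the p of 0.00202 is not a test free of it. Windows matched on covered percent in WT were 95.4% covered in mutant controls. The ARR7 region from 6575983 to 6578460 and the ARR16 regions had no peak in any of the 4 mutant libraries. ARR6, in the region from 25251943 to 25253020 on chromosome 5, was 41.9% ± 1.0 covered in mutant controls and 92.3% ± 9.1 in WT controls, and IAA3, in its region of 938 bp, 34.8% ± 20.4 and 80.9% ± 15.3.

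For the 685 shoot regions the level was 6.04 percentage points lower in the mutant (exact permutation p = 0.00202, adjusted p = 0.00909). After subtracting each library's mean over all root regions, which was 57.1% ± 5.7 in WT and 52.6% ± 5.0 in the mutant, the differences of 7.59 and 6.04 became 3.09 (exact permutation p = 0.428) and 1.53. With the same number of widest peaks in each library the first was 7.78 (exact permutation p = 0.00202, under the same limit of the choice on WT).

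The mutant regions also differed between treatments in the WT direction. Root regions were 88.5% ± 1.3 covered in mutant control and 91.5% ± 1.3 with BA (n = 2 each, exact permutation p = 0.333, the smallest possible), and 96.1% ± 1.5 and 99.0% ± 0.57 in WT (n = 4 each). The authors chose the regions on the WT libraries, so the WT difference of 2.89 is a description. A test against the mutant difference is therefore not given. Windows matched on WT control and BA covered percent differed by 2.72 (central 95% of 1000 sets 2.57 to 2.89), which the matching set in advance. WT values lie near the 100% limit of the measure. In the 296 regions that BA covered more in WT, picked by their WT values and without matched windows, the mutant had 75.7% ± 3.5 in control and 81.3% ± 2.3 with BA. At single genes, ARR5 in its region of 2358 bp had 70.8% ± 8.8 and 87.1% ± 12.2 in the mutant, and ARR6 in its region of 1078 bp 41.9% ± 1.0 and 85.0% ± 4.4. ARR7 in its flanking region had 20.4% ± 4.1 and 32.9% ± 0.26. The shoot regions were 74.2% ± 1.7 and 73.6% ± 1.4 covered in mutant control and BA, a difference of -0.538 that was 3.52 after subtraction of the mean over all regions.

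**Figure D3:**
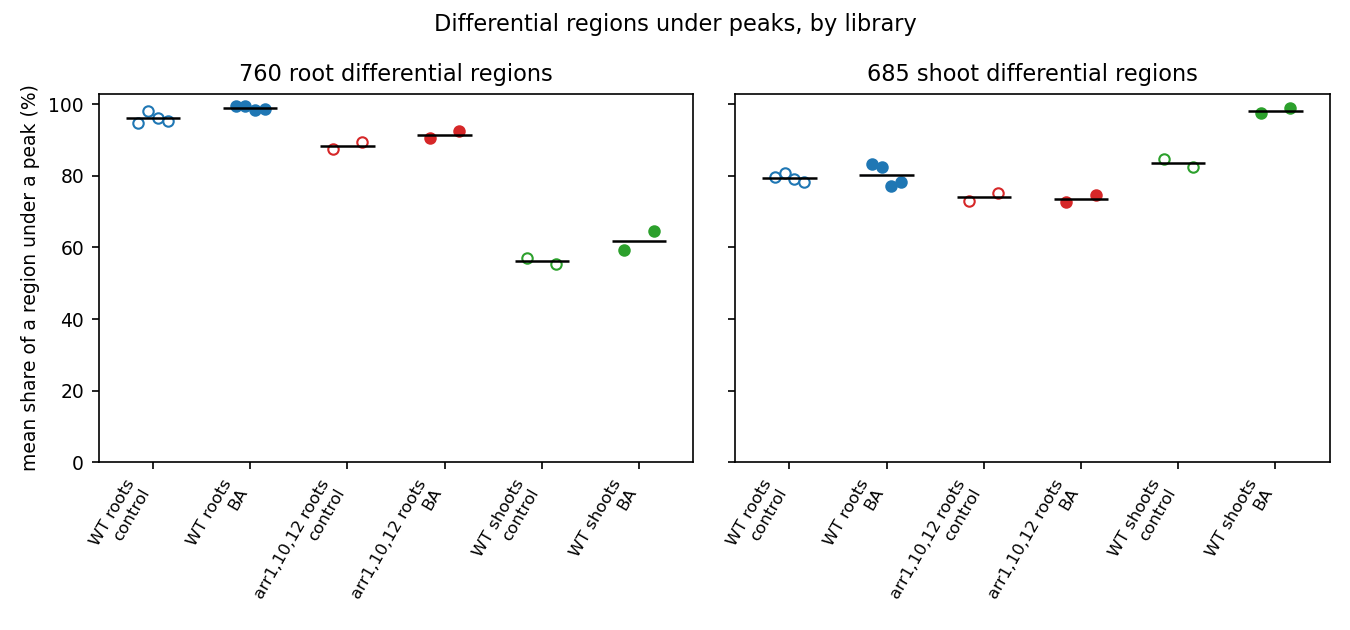
Mean covered percent (vertical axis, %) of the 760 root (left) and 685 shoot (right) differential regions in each library; points are libraries, filled for BA and open for control, and lines are group means. In the root regions WT roots average 96.1% and 99.0%, arr1,10,12 roots 88.5% and 91.5% and shoots 56.3% and 61.9%.

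All 10 type-A genes had the lower mean in the mutant. Their windows were 57.5% ± 7.7 covered in WT and 44.4% ± 2.2 in arr1,10,12 (exact permutation p = 0.0101, adjusted p = 0.0455). This call did not hold when any 1 of the 12 libraries was left out (differences 11.6 to 14.3). For 3 of the 10 the difference passed when adjusted over the list alone and for 0 over all genes: ARR3 (43.7% ± 4.6 and 33.0% ± 3.4), ARR6 (71.2% ± 7.7 and 55.0% ± 7.0) and ARR17 (56.6% ± 8.0 and 35.5% ± 6.1). ARR7 had 58.5% ± 25.2 and 27.4% ± 3.1, and ARR16 14.2% ± 12.7 and no peak in the mutant. These WT and mutant values, and those of the next paragraph, pool BA and control libraries, so the SD also holds the BA difference. In controls the type-A windows were 51.0% ± 2.1 covered in WT and 42.7% ± 1.4 in the mutant. With BA they were 64.0% ± 4.6 and 46.1% ± 0.94. ARR7 had 35.9% ± 3.0 and 25.0% ± 1.5 in controls, and 81.1% ± 10.6 and 29.8% ± 1.9 with BA. A mean of 9.62 ± 0.74 type-A genes had a peak in WT and 8.25 ± 0.50 in the mutant (exact permutation p = 0.0182, adjusted p = 0.164). The BA difference over the type-A windows was 12.96 percentage points in WT roots and 3.45 in the mutant, and the difference between them, 9.50, did not pass (exact permutation p = 0.105, adjusted p = 0.769 over 42 tests).

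The early response list was lower in the mutant as well, 50.03% ± 2.2 in WT and 44.1% ± 2.7 in arr1,10,12 (exact permutation p = 0.00202, the smallest possible, adjusted p = 0.0182). Of its 14 genes, 9 had the higher mean in WT and 5 in the mutant, and 7 passed when adjusted over the list alone and 0 over all genes, all 7 higher in WT: CRF4, CRF5, LBD3 (51.7% ± 7.5 and 31.5% ± 5.8), GATA22, IAA3 (37.5% ± 6.4 and 24.1% ± 7.4), the expansin gene EXPA1 (34.3% ± 9.8 and 14.5% ± 7.6) and HBI1 (28.9% ± 2.6 and 19.4% ± 5.6). This call, for covered percent of gene windows, cytokinin response factors and other early response genes, WT against arr1,10,12 roots (5.97), did not hold without arr1,10,12 control 1 (4.75), BA 1 (5.87) or BA 2 (6.38), or with the gene body alone (4.17). Left-out mutant libraries also ended the unadjusted calls of CRF5 (control 1 or 2) and GATA22 (control 1, BA 1 or BA 2). In the metabolism list CKX6 passed over the list alone (43.6% ± 3.7 and 24.8% ± 3.6). The mutated genes had 57.0% ± 7.8 and 53.8% ± 6.2 (ARR1), 41.3% ± 4.1 and 37.996% ± 2.8 (ARR10) and 51.3% ± 5.0 and 39.7% ± 3.4 (ARR12) in WT and mutant roots, of which ARR12 passed over the list alone (exact permutation p = 0.00202). The differences for the other lists did not pass: 1.60 for type-B genes, 1.44 for receptors and phosphotransfer proteins, 1.71 for metabolism, 3.08 for auxin, 0.954 for root identity, 0.188 for photosynthesis and -1.12 for broadly used genes. Over all 27432 genes, 2464 had an unadjusted p under 0.05 and 0 passed.

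**Figure D4:**
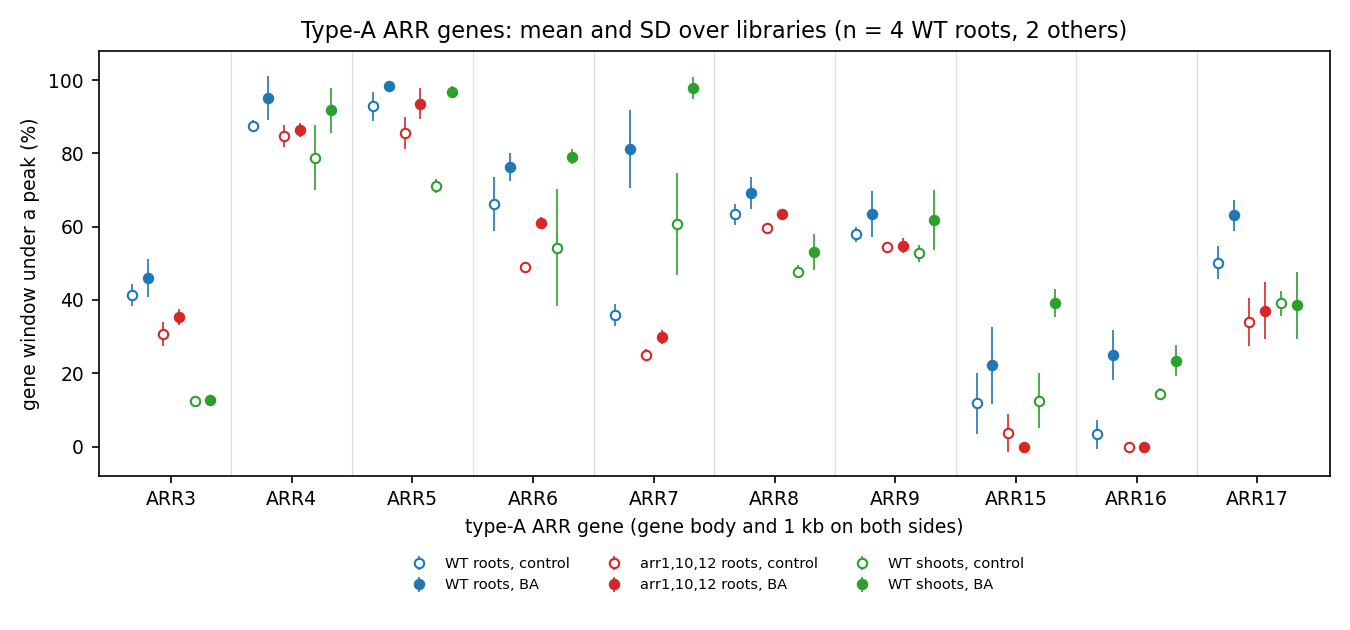
Covered percent (vertical axis, %) of the window of each type-A ARR gene, as mean and SD over libraries (4 per point in WT roots, 2 in arr1,10,12 roots and in WT shoots), open for control and filled for BA. ARR7 goes from 35.9% to 81.1% in WT roots and from 25.0% to 29.8% in arr1,10,12 roots.

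Whole peaks gained or lost in the mutant were few. Of 30896 regions, 38 had a peak in all 8 WT and no mutant library, the widest at AT3G45093 (chromosome 3, 16497130 to 16499275), CKL6, MLP34, AT3G27400, AT2G18480, AT2G22790, AT3G25570, AT3G55720, TLL1 and AT2G43470. The reverse held for 12 regions, at AT1G37113, AT1G28660, AT1G36970, AT4G02950, UMAMIT17, MLO9, the auxin efflux gene PIN4 (chromosome 2, 184389 to 184897), HB21 and AT5G24170 among others. The midpoint was over 1 kb from CKL6, AT2G22790 and AT3G55720 in the WT set. In the mutant set it was so for AT1G37113, AT4G02950, MLO9 and AT5G24170. By Fisher's exact test, 252 regions had an unadjusted p under 0.05 and 0 passed, for which 1249 fully separated regions would be needed. Among the 15 splits that keep replicate pairs together, too few for a share under 0.05, the real one separated 50 regions and the highest other, WT replicates 1 and 2 against the rest, 120. The separated regions numbered 82 without WT BA 3, 87 without arr1,10,12 BA 1 and 77 without arr1,10,12 BA 2. Peak sets were more similar within (0.797) than between genotypes (0.784, one-sided exact permutation p = 0.0323), a similarity within minus between, genotype, of 0.0125 that did not pass without WT control 2, WT BA 1, WT BA 2 or any 1 mutant library (0.00891 to 0.0131). Libraries of the same replicate number all lie within a genotype and raise the value within. They had 0.819 in WT roots and 0.833 in arr1,10,12 roots, and those of other numbers 0.790 and 0.796. Peak number (33310.5 ± 1584 and 32716.5 ± 1070, exact permutation p = 0.547) and covered length (26.4 ± 1.5 and 25.4 ± 1.5 Mb, exact p = 0.287) did not differ beyond the spread. Within the mutant, 652 of 29303 regions separated BA from control, and the other splits 531 and 1698.

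Last, roots and shoots were compared, the setting in which both responses take place. Most root identity genes were more covered in roots and most photosynthesis genes in shoots, though many had a peak in both tissues. Of 20 root identity genes, 18.1 ± 0.64 had a peak in roots and 11.25 ± 1.5 in shoots, and of 30 photosynthesis genes 23.4 and 27.5. PHT1;1, a root phosphate transporter gene, was 64.3% ± 12.4 covered in the 8 root libraries and had no peak in the 4 shoot libraries, as had RHD6, a regulator of root hairs (40.2% ± 2.1 in roots). RBCS1B, RBCS2B and RBCS3B, which encode the small subunit of Rubisco, had no peak in roots and were 64.9% ± 12.1, 83.4% ± 11.4 and 76.1% ± 8.3 covered in shoots. In the cytokinin pathway some genes differed in degree: AHP1 (82.9% ± 2.2 in roots and 5.99% ± 1.5 in shoots), CYP735A2 (38.5% ± 17.9 and no peak), CKX2 (11.7% ± 3.0 and no peak) and CFB (90.4% ± 4.7 and 25.9% ± 6.3) were more covered in roots, and HBI1 (28.9% ± 2.6 and 77.8% ± 9.9) and GATA21 (14.0% ± 3.2 and 46.4% ± 9.0) in shoots.

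Root identity windows were 28.7% ± 3.3 covered in roots and 8.12% ± 0.43 in shoots, and photosynthesis windows 22.7% ± 1.1 and 45.6% ± 4.2 (exact permutation p = 0.00202, the smallest possible, adjusted p = 0.00364 for each). Of 20 root identity genes, 17 were higher in roots when adjusted over the list alone and 14 over all genes. Of 30 photosynthesis genes, 20 were higher in shoots over the list alone and 20 over all genes, among them LHCB2.1 (6.78% ± 3.1 and 78.5% ± 10.5) and the chloroplast regulator GLK1 (2.52% ± 4.4 and 59.0% ± 7.5), while LHCB4.1 and MUTE were higher in roots over the list alone (MUTE not without shoot control 2 or shoot BA 1). Type-B genes (21.3% ± 1.1 and 14.8% ± 1.4), receptors and phosphotransfer proteins (36.3% ± 1.0 and 26.1% ± 3.9) and metabolism genes (37.8% ± 2.8 and 31.2% ± 2.7) were higher in roots (exact permutation, adjusted p = 0.00364 for each). Root libraries covered more in general, 27.9% ± 1.8 of the window against 23.2% ± 1.9 over all 27432 genes, a difference of 4.73 percentage points. In percentage points those of type-B genes (6.50) and metabolism genes (6.54) were little above it and that of receptors and phosphotransfer proteins was 10.2. As a percent of the root value the difference was 16.9 over all genes and 17.3 for metabolism genes. On that scale it was 30.5 for type-B genes and 28.2 for receptors and phosphotransfer proteins. None was tested against the difference over all genes. In the auxin list PIN2 was higher in roots (61.4% ± 4.1 and 12.4% ± 3.5, exact permutation p = 0.00202). Over the list alone the counts higher in roots and in shoots were 4 and 0 of 11 type-B, 3 and 1 of 9 receptor and phosphotransfer, 7 and 4 of 21 metabolism, 4 and 7 of 14 early response, 5 and 5 of 14 auxin, 3 and 0 of 10 type-A and 3 and 0 of 7 broadly used genes. The type-A list did not differ (57.5% ± 7.7 and 51.9% ± 9.3, exact permutation p = 0.287), nor did early response (50.03% ± 2.2 and 54.4% ± 4.5, adjusted p = 0.0591). Auxin (40.6% ± 2.5 and 36.9% ± 2.2) and broadly used genes (59.5% ± 3.4 and 54.0% ± 4.1) had an adjusted p of 0.0416 each, calls that did not hold with the gene body alone or with the same number of peaks. Over all 27432 genes, 8873 were higher in roots and 2420 in shoots.

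Of 32001 regions, 1715 had a peak in all 8 root and no shoot library and 901 the reverse, all 2616 with an adjusted p of 0.0247 by Fisher's exact test. The widest root regions lay at AT4G15740 (chromosome 4, 8964218 to 8967070), RAX2 (chromosome 2, 15486141 to 15489082), AT1G77330, AT4G28830, the laccase gene LAC7, AT5G43520, the marneral synthase gene MRN1, AT1G53970, the ammonium transporter gene AMT1;3 and AT3G16432. For AT1G77330, AT4G28830, MRN1 and AMT1;3 the midpoint was over 1 kb from the gene. The widest shoot regions lay at the lipid transfer gene LTP (chromosome 2, 6518116 to 6522185), RLP19, WRR4, RBCS2B (chromosome 5, 15379463 to 15384016), AT2G41945, AT2G10940, AT1G51805, AT1G43605, MYB94 and AT2G29290. The midpoint was over 1 kb from any protein-coding gene in 25.1% of the root set and 27.1% of the shoot set. Peak sets had a Jaccard index of 0.789 within and 0.595 between the tissues (one-sided exact permutation p = 0.00202). Root peaks covered more of the genome than shoot peaks (26.4 ± 1.5 against 21.8 ± 1.5 Mb) and were wider (median 518 ± 16 against 447 ± 20 bp; exact permutation p = 0.00202, the smallest possible, adjusted p = 0.00606 for each). Without any 1 shoot library 0 regions passed the adjustment, as 3 shoot libraries give a larger smallest p, while 2853 to 2924 were fully separated.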

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

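Among the tests in this part, the count of splits of the WT root libraries and the splits that keep replicate pairs together were chosen only after the results were seen.

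Of 42 groups of 4 libraries and measures, 5 held a library far from the other 3, and chance gives about 1 in 20. In WT roots, replicate 1 had the most peaks in both treatments, 35228 with BA (median of the others 32171) and 36358 in control (32675). Control 1 also had more of its peaks in gene bodies (47.1%, others 39.0%) and fewer within 1 kb of a gene (37.7%, others 45.2%). The windows of the early response list, which holds genes such as LBD3 and HBI1, were more covered in WT root control 2 (52.6%) than in the other controls (48.2%).

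For the root identity genes, the difference between BA and control was flagged as unlike between tissues. It was -4.22 percentage points in WT roots and 0.658 in shoots, -4.88 between them (exact permutation p = 0.0333). In shoots these windows were 7.79% covered in control and 8.45% with BA, which leaves less room for a fall. Covered length also differed by -1.71 Mb in WT roots and 0.758 Mb in shoots, and the list was not set apart from that shift. The difference of -4.88 did not pass the adjustment over 42 tests of such differences (exact permutation, adjusted p = 0.769).

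In WT roots BA and control separated 26 regions, and 18 of the 35 splits of the 8 libraries separated as many, so over all splits chance is not excluded for this count. The highest other split, replicates 1 and 2 against 3 and 4, separated 213, several times the real count, which points to a structure of the samples by replicate. Most of these splits part fewer replicate pairs than the real one. The 8 splits that part every pair are too few for a share under 0.05; the real one separated 26 and the others 5 to 21. With the same number of widest peaks in each library the replicates still separated 149 regions and the treatments 29, which argues against different numbers of peaks as the whole cause. The labels give no batch, and no biological explanation was tested.

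For roots against shoots, 1 of 100 splits of the 12 libraries, the real one, gave 2616 regions past the adjustment; the highest of the others gave 0, with 17 fully separated. For WT against arr1,10,12 roots, 1 of 100 splits, the real one, separated 50 regions and the highest of the others 20, and no single region passed the adjustment. Most of these splits break replicate pairs, which both real splits keep together. The 15 splits that keep all 6 pairs together are too few for a share under 0.05. Among them roots against shoots fully separated 2616 regions and the highest other 111, and WT against arr1,10,12 roots separated 50 and the highest other 120. In both cases the highest other was WT root replicates 1 and 2 against the rest, which points to the same structure by replicate, and the count of 50 is not set apart from it.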

How the results depend on the processing

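The gene body alone, 0.5 kb flanks, the covered percent of gene windows, and leaving out both WT root libraries of replicate 1 were chosen only after the data were seen. Of 3149 alternatives of 238 results, 2828 kept the direction and the side of the threshold, or without a test stayed within their spread; 234 lost the threshold, 13 gained it, 27 moved and 47 reversed. No alternative changed 140 of the results. Except where the construction of an alternative is given, the cause was not tested. Alternatives for organelle peaks (the lists hold none), windows at the start of transcription (no strand) and the motif (no genome) were not run. Limits set by depth cannot be given, as the lists hold no read numbers. In shoots and arr1,10,12 roots the correlations of these deviations between libraries with the same number (0.324 and 0.345) rest on 2 pairs. These are too few to tell whether the numbers pair the libraries. Splits by number separated 1647 and 1698 regions, and treatment 631 and 652. The changed values follow, with the range on leaving out 1 library at a time.

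In peak number, BA against control, WT roots, the sign reversed without control 1 (-1295 to 360.2). For percent of peaks in gene bodies, BA against control, WT roots, the sign reversed without both replicates 1 (1.14) and without BA 2 or control 1 (-1.18 to 1.54). As for percent of peaks elsewhere, BA against control, WT roots, the sign reversed without BA 3, BA 4 or control 2 (-0.251 to 0.0995). As for regions separated by BA and control, WT roots, the value moved with 50% of the region covered (46), merged within 150 bp (14), without both replicates 1 (172) and without any 1 library (41 to 90). With respect to similarity within minus between, treatment, WT roots, the sign reversed by reciprocal overlap (0.000626), without both replicates 1 (0.00152) and without control 2, control 3 or control 4 (-0.00927 to 0.00294). For percent of differential regions with a direction that are more covered with BA, root, the value moved in the wider part of the list (89.95). As for root differential regions, BA minus control in WT roots, the call, which restates the authors' choice, was lost by regions with at least 1 bp covered (0.559), after subtraction (8.9998), in replicate blocks (2.89), without both replicates 1 (2.32) and without BA 1, BA 2, BA 3 or BA 4 (2.46 to 3.55). With respect to root differential regions, change in WT roots minus change in WT shoots, the sign reversed after subtraction (5.64). Likewise for shoot differential regions, BA minus control in WT roots, the sign reversed without both replicates 1 (-0.0918) and without BA 1 (-0.173 to 1.87). Regarding number of genes with a peak, root identity, BA against control, WT roots, the sign reversed without BA 3 (-0.583 to 0.0833). With respect to number of genes with a peak, photosynthesis and leaf identity, BA against control, WT roots, the sign reversed at 2 kb (0.25) and without BA 2 (-0.833 to 0.5). As to covered percent of gene windows, receptors and phosphotransfer proteins, BA against control, WT roots, the sign reversed without BA 1 or control 4 (-0.211 to 0.720). Likewise for covered percent of gene windows, cytokinin metabolism, BA against control, WT roots, the sign reversed at 2 kb (-0.551), without both replicates 1 (-0.624) and without BA 1 or control 4 (-0.776 to 1.87). In replicate blocks 4 pairs cannot give an exact p below 0.125.

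Regarding peak number, roots against shoots, a call was gained in peaks of median width or more (3165.25). With respect to percent of peaks in gene bodies, roots against shoots, the sign reversed without shoot BA 1 (-3.06 to 0.679). As to percent of peaks elsewhere, roots against shoots, the sign reversed without shoot BA 2 (-0.439 to 0.0273). Likewise for regions past the adjusted threshold, roots against shoots, the value moved with 50% of the region covered (3981), in controls only (0), without both replicates 1 (0) and without shoot control 1, shoot control 2, shoot BA 1 or shoot BA 2 (0 to 2840). Also, for regions fully separated, roots against shoots, the value moved with 50% of the region covered (3981) and in controls only (4314). For genes of the list cytokinin metabolism with a shoot differential region, the call was lost at 2 kb (3). As for genes of the list cytokinin response factors and other early response genes with a shoot differential region, the call was lost in gene bodies (1). Also, for number of genes with a peak, type-B ARRs, roots against shoots, the sign reversed at 2 kb (-0.125). In number of genes with a peak, auxin transport and response, roots against shoots, the sign reversed without shoot BA 1 (-0.125 to 0.25). For covered percent of gene windows, cytokinin response factors and other early response genes, roots against shoots, a call was gained at 2 kb (-6.12), at equal peak number (-4.83) and without root BA 1 or shoot control 2 (-6.53 to -3.03). As for covered percent of gene windows, auxin transport and response, roots against shoots, the call was lost in gene bodies (0.605), at 2 kb (3.05), at equal peak number (3.27), without both replicates 1 (3.51) and without any 1 library but root BA 3, root BA 4 or shoot control 1 (2.71 to 4.43). Regarding covered percent of gene windows, broadly used genes, roots against shoots, the call was lost in gene bodies (6.12), at equal peak number (5.30), without both replicates 1 (4.67) and without any 1 library but root control 4, root BA 4 or shoot BA 1 (3.78 to 7.09). Regarding covered percent, CRF5, roots against shoots, the sign reversed in gene bodies (-3.40). By Fisher's exact test the adjusted p of the metabolism list was 0.0107 to 0.0722 over its alternatives, and that of the early response list reached 0.416. The 0 in controls follows from 4 against 2 libraries (smallest Fisher p 0.0667, exact), and without 1 shoot library the adjustment needs more separated regions than were found.

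Likewise for peak number, WT against arr1,10,12 roots, the sign reversed without both replicates 1 (-233.5). Also, for median peak width bp, WT against arr1,10,12 roots, the sign reversed in peaks of median width or more (-16.375). In percent of peaks in gene bodies, WT against arr1,10,12 roots, a call was gained without both replicates 1 (-4.00) and without root control 1 (-3.92 to -1.97). For percent of peaks elsewhere, WT against arr1,10,12 roots, a call was gained at 2 kb (0.477), without both replicates 1 (0.804) and without root control 1 or arr BA 1 (0.756 to 1.00). Regarding regions separated by BA and control, arr1,10,12 roots, the value moved merged within 150 bp (399). As to similarity within minus between, genotype, the call was lost without any 1 library but root control 1, root control 3, root control 4, root BA 3 or root BA 4 (0.00891 to 0.0179). In regions fully separated, WT against arr1,10,12 roots, the value moved in controls only (498), without both replicates 1 (76) and without root BA 3, arr BA 1 or arr BA 2 (51 to 87). Regarding root differential regions, change in WT roots minus change in arr1,10,12 roots, the sign reversed at equal peak number (0.373), after subtraction (1.87) and without root control 2, root BA 3, arr control 1 or arr BA 2 (-1.13 to 0.762). As to root differential regions, level in WT minus arr1,10,12 roots, the call, which the authors' choice favours, was lost after subtraction (3.09). Also, for shoot differential regions, BA minus control in arr1,10,12 roots, the sign reversed by regions with at least 1 bp covered (0.146), after subtraction (3.52) and without arr control 2 or arr BA 1 (-1.72 to 0.645). In shoot differential regions, level in WT minus arr1,10,12 roots, the call was lost after subtraction (1.53). With respect to number of genes with a peak, auxin transport and response, WT against arr1,10,12 roots, the sign reversed without arr control 1 (-0.125 to 0.25). As to covered percent of gene windows, type-A ARRs, WT against arr1,10,12 roots, the call was lost in gene bodies (9.13), at equal peak number (12.7), without both replicates 1 (12.5) and without any 1 library (11.6 to 14.3). Likewise for covered percent of gene windows, type-B ARRs, WT against arr1,10,12 roots, a call was gained without arr control 2 (0.830 to 2.21). Also, for covered percent of gene windows, receptors and phosphotransfer proteins, WT against arr1,10,12 roots, a call was gained without arr control 2 (0.571 to 2.46). In covered percent of gene windows, cytokinin response factors and other early response genes, WT against arr1,10,12 roots, the call was lost in gene bodies (4.17) and without arr control 1, arr BA 1 or arr BA 2 (4.75 to 6.88). For covered percent of gene windows, root identity, WT against arr1,10,12 roots, the sign reversed in gene bodies (-0.216). As for covered percent of gene windows, photosynthesis and leaf identity, WT against arr1,10,12 roots, the sign reversed without both replicates 1 (-0.149) and without root control 1, root control 3 or arr BA 1 (-0.451 to 0.842).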

Other observations

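Among the tests in this part, the matched windows in the same arr1,10,12 libraries with the same number of peaks as a test of fewer or narrower peaks, the counts of single regions by genotype and the genes named from them were chosen only after the results were seen.

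Values of single root differential regions in the mutant follow. In 38 of the 760, every arr1,10,12 library was below every WT root library; a given set of 4 libraries is lowest in 0.202% of the splits, if pairs are not kept together. With the same number of widest peaks these were 37 regions, all among the 38. The authors chose the regions on the WT libraries, and 413 are fully covered in each of them, so that higher mutant values were ruled out for most and the count shows no direction. The regions nearest to AT1G14630 (chromosome 1, 5018463 to 5018660, 99.1% ± 2.5 in WT) and AT2G22790 (98.1% ± 5.3), both over 1 kb away, had no peak in the mutant. ARR3 had 100% and 61.98% ± 31.6, ARR7 95.9% ± 5.3 and 76.8% ± 2.3, LBD3 91.6% ± 8.6 and 64.8% ± 14.9, and CKX5 96.9% ± 3.6 and 80.7% ± 7.6. ACS7, an ethylene synthesis gene, had 93.2% ± 11.2 and 57.6% ± 0.13. CYP708A2 (98.2% ± 5.2 and 71.0% ± 9.6 in one of its regions), CYP705A5 (100% and 87.7% ± 1.4) and CAS1 (96.8% ± 4.9 and 54.4% ± 1.7) were others, named without a test of any gene group. For ACS7, CYP708A2 and CYP705A5 the midpoint was over 1 kb from the gene.

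Outside the fixed lists, both tissues had differential regions at ABCG14, a cytokinin exporter gene, and at IDD2, EIL1, EBF2, GSTU19, XTH31 and LBD38 among the 90 genes with a region of both lists. These genes were picked from the 90 after the data were seen. The ABCG14 window was 57.2% ± 2.9 covered in WT root controls and 63.2% ± 11.5 with BA, and 39.8% ± 6.1 and 50.9% ± 12.4 in shoots. IDD2 had 65.3% ± 1.5 and 70.9% ± 4.7 in roots, and 53.995% ± 12.2 and 68.5% ± 2.0 in shoots. These differences were not tested.

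The lower coverage of root differential regions in arr1,10,12 was weighed against 3 technical explanations. If it came from choosing regions on WT libraries, windows matched in WT would be as low in the mutant, but mutant controls had 88.5% in the regions and 95.4% in matched windows (central 95% of sets 94.6 to 96.2). The test of fewer or narrower peaks written before the result, subtraction of the mean over all regions, met what that explanation predicts: WT and mutant had 97.6% ± 1.9 and 89.99% ± 2.1 before it, and 40.5 ± 6.5 and 37.4 ± 5.3 after it (3.09, exact permutation p = 0.428). The call ended because the difference became smaller and the spread between libraries larger. With the same number of widest peaks the difference was 7.78 (exact permutation p = 0.00202, pairs not kept together, regions chosen on WT). The matched windows come from the same mutant libraries. Together these values argue against fewer or narrower peaks as the whole cause, while a part played by them stays open. Weak peaks would make the regions low in WT libraries not used for matching, but they were 2.87 above windows matched on replicates 1 and 2 and 1.88 above those matched on 3 and 4. The authors chose the regions on all 8 WT libraries and the windows were matched on 4, which favours this outcome. The lists also hold no peak height, so this test cannot exclude weak peaks. In the 4 mutant libraries the regions minus these windows gave -2.65 and -5.43, so the size of the gap depends on the matching. A lower accessibility without ARR1, ARR10 and ARR12 also stays open and was not tested apart from these.

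The mutant difference between BA and control at these regions was 3.07 percentage points, against -0.283 in matched windows (central 95% of sets -0.983 to 0.413), which argues against the choice of regions on WT libraries as its source. These intervals cover the drawing of windows and not the spread between 2 and 2 libraries, so a remaining response without the 3 regulators may be present but is not established.

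The number of type-A genes with a root differential region, 9 of 10, was compared with 10000 sets of 10 genes matched on window length and covered length. The sets had a mean of 0.463 and a highest count of 4, and for the 8 genes of the shoot list a mean of 0.671 and a highest count of 4. This argues against long or widely covered gene windows as the source of the regions at ARR5, ARR7 and their relatives, and a response of these genes to BA may be a candidate explanation.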
